A study of Caenorhabditis elegans with 2 samples.

How the data were processed

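ZAG-1 occupancy was measured by transcription factor ChIP-seq in whole third-stage larvae of C. elegans strain OP83, with libraries of 150 to 350 bp per the labels. Both samples belong to 1 group, and their replicate numbers, 1 and 2, are the biological replicate numbers in the labels.

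The authors deposited region lists in the ce10 and ce11 builds. Each replicate list was made from the alignment of that replicate and a control file, a further list from both alignments and the control, and the optimal set from these lists by the irreproducible discovery rate (IDR), per the labels and the notes deposited with the lists. The aligner, the caller and the IDR threshold are not given in the sources used here. The replicate and joint lists include background regions on purpose, so their lengths do not count binding sites. The control reads were not analysed here.

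The values are a signal score for each region, set by the authors against the control and not scaled between lists, and a −log10 q-value, which the authors deposited as 1.38 for all 357 optimal regions and which therefore ranked nothing. The deposited p-value column held a placeholder of -1. The other deposited column gives the summit, which was the region centre for 347 of the 357. Scores were used to describe and rank regions within a list. Depth is unknown, so no interval for a score can be given, and intervals on shares cover the counting of regions only. The optimal set was the same as the 357 highest regions of the joint list.

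Analysis used ce11, which is the WBcel235 assembly, with Ensembl release 115 gene models; the ce10 lists entered counts and overlaps only, and no coordinate was converted. Coordinates are 1-based. Scripts ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

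A region counted as found in another list when summits lay within 100 bp. Random placements kept each region on its chromosome and were drawn 10000 times, or 1000 times for shared regions. Placement tests were two-sided, apart from a one-sided test of recurring mitochondrial regions. A gene was bound when its protein-coding transcript start was the nearest to a summit and within 5000 bp, which 22 of 339 nuclear summits did not meet. The 31 gene lists and the rule for names were fixed before the data were examined; 9 of the 563 symbols written out in them matched no gene. Lists were tested by a two-sided Fisher's exact test against 19973 genes. Words were sought on both strands within 50 bp of the summit, and windows that left the chromosome were dropped. Adjusted p-values are by Benjamini-Hochberg, at 0.05.

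The rule for names took zag-1, unc-119, mec-3, egl-44 and egl-46, the genes of the 25 highest optimal regions, up to 4 bound members of a list past the threshold and 2 of any other list by score, and genes with 3 or more regions. The 11 mitochondrial regions among the 25 were not given to genes.

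The list test and the hexamer scan were tested on simulated data. With ribosomal protein genes drawn at 10 times the weight of other genes among 19973, their list was called in 97% of 100 runs, at 5 times in 47%, and at equal weight in 0%. With CACCTG planted in 20% of simulated summit windows, the scan of 2080 hexamers called it in 100% of 20 runs, and at 5% in 10%. A word in few summits would therefore mostly be missed by the scan. The simulated genes were drawn without regard to the length around them. The simulated windows were all shuffled from the flanks, so summit and flank windows had like base composition. The real regions and summit windows differ in this, so the runs do not give the rate of false calls in these data.

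Alternatives covered the build, the overlap rule, the 178 regions of highest score, each replicate alone, the promoter window, gene assignment, background, word window and control side. Restriction to nuclear summits and to regions found in both replicates was added after the data were seen.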

Results

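Binding of ZAG-1 was mapped by chromatin immunoprecipitation and sequencing in whole Caenorhabditis elegans at the third larval stage. ZAG-1 is the worm member of the ZEB family of zinc finger homeodomain proteins and is known for its part in neuronal differentiation. The animals, of mixed sex, came from strain OP83, which carries an eGFP-tagged zag-1 transgene in an unc-119 mutant background. The series holds 1 group of 2 biological replicates, so the comparisons are between the replicates, between bound regions and randomly placed regions, and between bound and unbound genes. No comparison between conditions could be made. The read depth of each library is unknown, because the files give regions and scores, not reads.

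The deposited optimal set held 357 regions in the ce11 build, with a median width of 384 bp. Their signal scores, which are the authors' own, ran from 33.002 to 393 with a median of 44.2. Longer lists that include background regions held 30000 regions for replicate 1, 26202 for replicate 2 and 10005 for both replicates together. The ce10 optimal set held 320 regions.

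The tagged gene itself had no region. None of the 4 lists placed a region at zag-1, at positions 3855843 to 3861569 of chromosome IV, where a region was given to the gene with the nearest protein-coding transcript start within 5000 bp. Within 20000 bp of zag-1 lay 3 regions of replicate 1 and 1 region of replicate 2, against medians of 13 and 12 in random windows of the same length (two-sided permutation p = 0.018 and 0.0096). Around unc-119, the rescue marker gene on chromosome III, lay 15 and 17 regions, against medians of 14 and 12 (permutation p = 0.85 and 0.34). Among the 5000 highest regions of each replicate, 1 lay in the zag-1 window in either replicate (permutation p = 0.79 for both). Random windows held a median of 2 of these, too few for a lower number to pass the threshold.

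**Figure D1:**
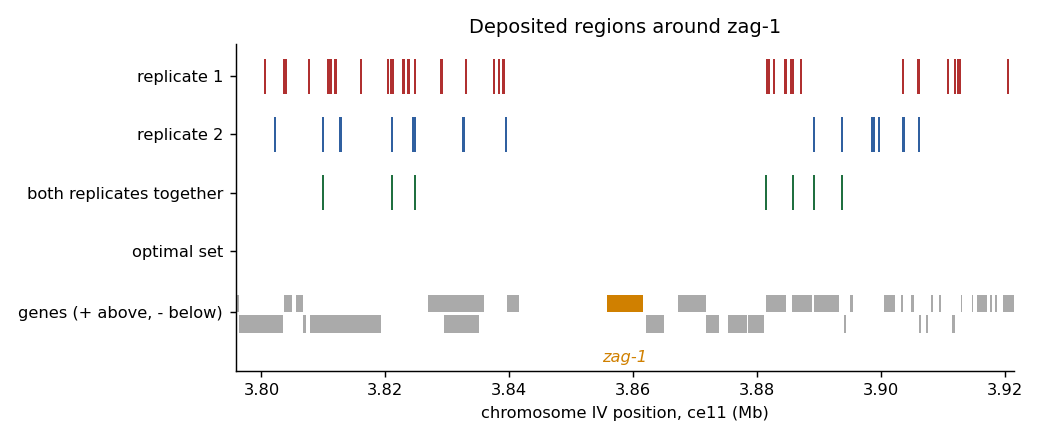
Deposited regions around zag-1 on chromosome IV in ce11, with position in Mb on the horizontal axis and 1 row for each of the 4 lists, each bar being a region; genes are drawn below by strand, with zag-1 in orange. The stretch around zag-1 holds no region of either replicate, and no optimal region lies in the part drawn.

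Genes known to act in touch receptor and FLP neuron fate, as zag-1 does, were looked up by name. No optimal region was placed at mec-3, a homeobox gene of touch receptor fate, or at egl-44 and egl-46, which act in FLP neurons. The list from both replicates together had 3 lower regions at egl-44, the strongest at position 5938786 of chromosome II with a score of 17.9 and rank 2298 of 10005. It held none at mec-3 or egl-46, and 1 at unc-119, with a score of 16.1 at rank 3516. In all, 0 of 24 genes of the touch receptor and FLP list were bound, where 0.364 were expected (upper bound of the exact interval 14.2%), so the list could not show a lower share.

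Most optimal regions were found in both libraries, from which the authors selected them for agreement. Of the 357 summits, 312 (87.4%, exact 95% interval 83.5 to 90.7) had a region summit within 100 bp in both replicates, against a mean of 1.56% and a maximum of 4.76% over 1000 random placements. Replicate 2 held 345 of them and replicate 1 held 324. Matched to the 357 highest regions of each replicate in place of the full lists, 155 optimal summits (43.4%) were found in both. Of the 357 highest regions of replicate 1, 153 (42.9%, interval 37.7 to 48.2) lay within 100 bp of one of the 357 highest of replicate 2, against a maximum of 3.08% over random placements.

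**Figure D2:**
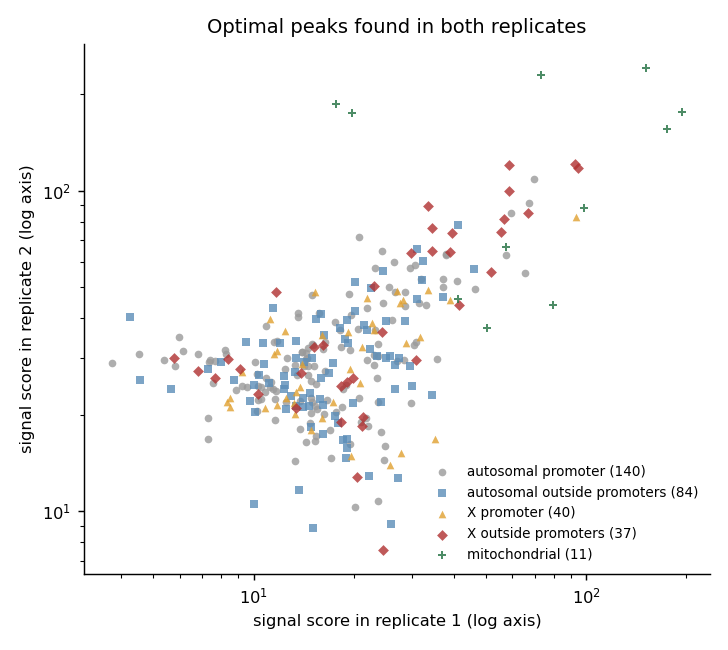
Signal score of each of the 312 optimal regions found in both replicates, replicate 1 on the horizontal and replicate 2 on the vertical log axis, with 1 point per region coloured by group. The points include 37 X-linked regions outside promoters and 11 mitochondrial regions.

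The highest scores fell mostly on mitochondrial DNA and on the X chromosome. Of the 25 highest regions, 11 were mitochondrial, and the first lay at positions 4566 to 4949 with a score of 393. The highest nuclear region lay at X positions 11094095 to 11094352, in an intergenic stretch 3970 bp from the start of W02H3.3, with a score of 212. It was followed by an intronic region of mom-1 at X positions 6296454 to 6296649, nearest to the start of cest-16, with a score of 210. The promoter region of rpl-3, a large-subunit ribosomal protein gene, scored 182 at positions 3867479 to 3867680 of chromosome III, with its summit 272 bp from the transcript start.

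Other nuclear regions among the 25 highest lay by nspc-17 (score 175), Y41G9A.17 (157), ZK1248.17 (155), F20B6.9 (150), ZK899.6 (128.9), ins-13 (120.0) and T27A8.7 (118). The promoter of cdc-48.1, which encodes an AAA ATPase of protein quality control, scored 143. A region 4869 bp upstream of xol-1, the switch gene of sex determination and dosage compensation, scored 137. The ribosomal protein gene rpl-35 scored 123.2. A region near K02D3.1, with a score of 174, lay 6037 bp from the start and was given to no gene.

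Regions lay mostly upstream of genes. Of the 357 summits, 217 (60.8%, interval 55.5 to 65.9) fell in promoters, taken as 1000 bp upstream to 100 bp downstream of a protein-coding transcript start. Random placements on the same chromosomes gave a mean of 25.9% and a maximum of 35.6% (two-sided permutation p = 0.0002, the smallest that 10000 placements can give). The median distance to the nearest start was 523 bp, against a placement mean of 1281 bp (permutation p = 0.0002). These values include the 18 mitochondrial regions. With nuclear summits only, the promoter share was 59.6%, against a placement mean of 23.4%. The median distance was then 596 bp, against 1370 bp (permutation p = 0.0002 for both). Of the 339 nuclear summits, 262 (77.3%, interval 72.5 to 81.6) were upstream of the nearest start, with a median signed distance of -248 bp.

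Coding exons and introns held fewer summits than random placements. Classes did not overlap and promoters were taken first, so the promoter excess (217 against 92.5) lowers the number left for the other classes. The lower numbers in other classes were not tested apart from this. As a share of the summits outside promoters, introns were close to random placements. By the same measure coding exons were lower and intergenic stretches higher. The lower intron number therefore does not show that introns were avoided. Coding exons held 5 summits, against 70.6 in random placements, and introns held 54, against 97.2 (adjusted permutation p = 0.00047 for both). Intergenic stretches held 67 against 75.7 (adjusted permutation p = 0.39) and noncoding genes held 11 against 10.7 (adjusted permutation p = 1). The 3' UTR class held 2 against 8.33 (adjusted permutation p = 0.04), and the 5' UTR class held 1 against 1.91 (adjusted p = 1).

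**Figure D3:**
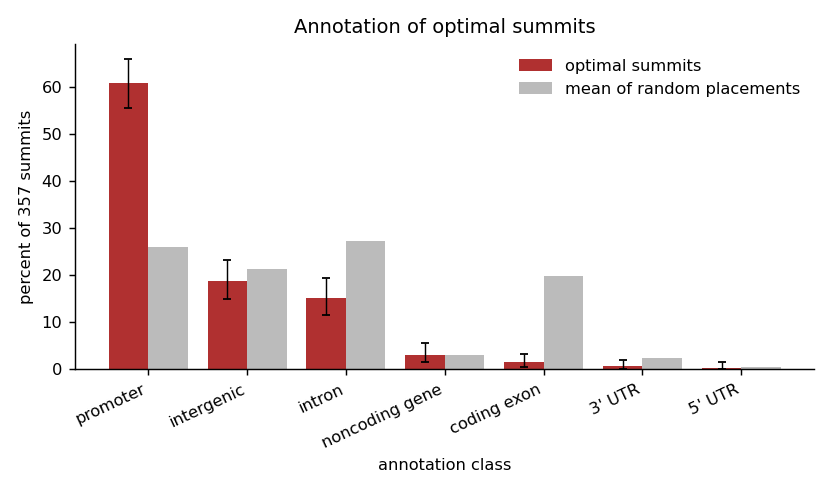
Percent of the 357 optimal summits in each annotation class (red, with exact 95% intervals) beside the mean of 10000 random placements (grey). Promoters hold 60.8% against 25.9%, and coding exons 1.40% against 19.8%.

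The X chromosome held more regions than its length. It carried 87 of the 339 nuclear summits (25.7%, interval 21.1 to 30.7), against 17.7% of nuclear length (exact binomial test, adjusted p = 0.000784 over 6 chromosomes). Chromosome V carried 37 (10.9%, interval 7.80 to 14.7), against 20.9% of length (exact binomial test, adjusted p = 1.06e-05). Shares on chromosomes I, II, III and IV, with 61, 44, 59 and 51 summits, did not pass the threshold (adjusted p from 0.116 to 0.290). Mitochondrial DNA, 0.0138% of the assembly, held 18 of the 357 regions (5.04%), of which 11 had a summit within 100 bp in both replicates. Copies of mitochondrial DNA per cell were not measured, so its length gives no expected number of regions.

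Ribosomal protein genes and heterochronic genes were bound more often than other genes, and chemoreceptor genes less often. A total of 303 of 19973 nuclear protein-coding genes (1.52%) had an optimal region. Bound means only that a region was placed at the gene. The series holds no library of another factor, so signal that any library would give could not be told apart from ZAG-1 binding. Among cytosolic ribosomal protein genes 13 of 83 were bound (15.7%, interval 8.61 to 25.3, odds ratio 12.6, Fisher's exact test, adjusted p = 1.11e-08 over 31 lists). Those of highest score were rpl-3, rpl-35, rpl-15 (94.8) and rps-20 (69.4).

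Heterochronic genes, which time larval cell fates, had 5 of 16 members bound (31.2%, exact interval 11.02 to 58.7, odds ratio 29.99, adjusted p = 3.06e-05). They were ain-1 (score 64.4), lin-66 (38.2), lin-28 (36.01), lin-41 (35.9) and lin-42 (33.4), the last named after its value was seen. These genes encode a microRNA complex component, a regulator of lin-28 translation, an RNA-binding protein, a TRIM-NHL protein and a period homologue. The region of lin-28 lay 27 bp inside the transcript start, and that of lin-41 in intergenic sequence 1525 bp upstream. From the share of all genes 0.243 bound members were expected. Random placements of the summits, which allow for the length around each gene, gave a mean of 0.722 (adjusted permutation p = 0.015). Against genes with a region of the joint list the odds ratio was lower, at 12.2 (Fisher's exact test, adjusted p = 0.00407). Among the 178 regions of highest score the list no longer passed the threshold (Fisher's exact test, adjusted p = 0.494).

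Nuclear genes of the respiratory chain had 4 of 47 members bound (8.51%, interval 2.37 to 20.4, odds ratio 6.11, Fisher's exact test, adjusted p = 0.0430). They were cox-5A (score 87.7), atp-1 (46.1), cox-5B (38.5) and atp-3 (33.3). This call was lost from the highest regions of replicate 1 alone (odds ratio 2.97, Fisher's exact test, adjusted p = 0.656) or replicate 2 alone (odds ratio 4.60, Fisher's exact test, adjusted p = 0.197). Chemoreceptor family genes had 2 of 1282 bound, srh-16 (34.5) and srsx-22 (34.2), where 19.4 were expected from the share of all genes (odds ratio 0.0955, Fisher's exact test, adjusted p = 1.09e-05). Random placements of the summits, which allow for the length around each gene, gave a mean of 10.3 (adjusted permutation p = 0.02).

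No neuronal list passed the threshold in the optimal set, and 1 passed in replicate 1 alone. Pan-neuronal synaptic and vesicle genes had 3 of 35 bound (Fisher's exact test, adjusted p = 0.0980), of which unc-108 scored 67.7 and egl-3 scored 56.9. From the highest regions of replicate 1 alone, 5 of 35 were bound, past the threshold (odds ratio 11.3, Fisher's exact test, adjusted p = 0.00121). From replicate 2 alone 3 of 35 were bound (Fisher's exact test, adjusted p = 0.113), and the difference between the replicates was not tested. Axon guidance genes had 3 of 56 (Fisher's exact test, adjusted p = 0.236), with unc-76 at 60.7 and unc-115 at 50.02. Neuropeptide genes had 1 of 102, nlp-40. The GABA, acetylcholine, glutamate, monoamine and nicotinic receptor lists had 0 of 14, 13, 21, 25 and 32. The expected number was at most 0.485 in each of these, so they could not show a lower share. The 9 neuronal lists together had 7 of 318 genes bound (2.20%, interval 0.889 to 4.48, odds ratio 1.47, Fisher's exact p = 0.346).

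Homeobox genes had 0 of 97 bound (upper bound of the exact interval 3.73%), against 1.47 expected (Fisher's exact test, unadjusted p = 0.409). The bHLH list had 3 of 42 members bound, hif-1, hlh-11 and lin-42 (Fisher's exact test, adjusted p = 0.133). Of these lin-42, which is also in the heterochronic list, encodes a period homologue without a bHLH domain and was put in this list in error, so 2 bHLH genes were bound. Insulin-like genes had 2 of 39, ins-13 and ins-39 (Fisher's exact test, adjusted p = 0.457). Nuclear hormone receptor genes had 4 of 274, led by nhr-88 and nhr-3. Single members were bound among Wnt and Notch genes (mig-5, of 40), histone genes (his-37, of 50), proteasome and heat shock genes (hsp-1, of 52), germline genes (ego-1, of 59) and collagen genes (col-94, of 176), each with an adjusted p of 1.

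No member was bound in the lists for body wall muscle (44 genes), pharynx (18), intestine (36), epidermis and seam (34), glia (22), cilia (47), potassium channels (74), innexins (25) and DEG/ENaC channels (28). The expected number was below 1.13 in each, so these lists could not show a lower share. The gene pqn-41 held 3 optimal regions, all in its introns, with scores of 100.5, 59.6 and 38.3.

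**Figure D4:**
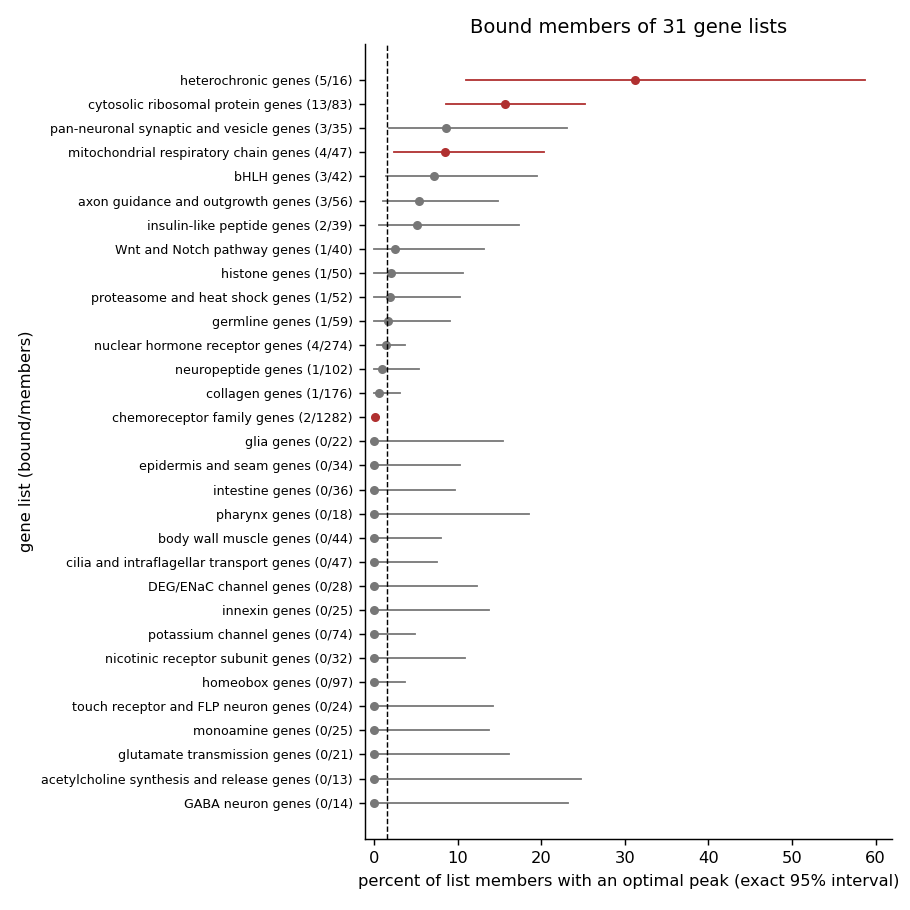
Percent of the members of each of 31 gene lists with an optimal region, with exact 95% intervals; red marks lists past an adjusted p of 0.05, and the dashed line is the share of all genes, 1.52%. Heterochronic and ribosomal protein genes lie to its right, and chemoreceptor genes lie to the left of the line at 0.156%.

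The word CACCTG, bound by vertebrate ZEB proteins, was not more frequent at summits. It lay within 50 bp of 7 of 356 summits (1.97%, interval 0.794 to 4.01) and in 9 windows centred 500 bp to the left (2.53%, exact McNemar test, adjusted p = 0.970 over 7 words). Promoter summits had it in 2 of 217 and other summits in 5 of 140 (Fisher's exact p = 0.116). Regions with a score above the median had it in 2.81% and the rest in 1.12% (Fisher's exact p = 0.284).

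The word GAGAGA was more frequent at summits instead. GAGAGA lay within 50 bp of 132 summits (37.1%, interval 32.05 to 42.3) and in 19 left windows (5.34%, exact McNemar test, adjusted p = 1.31e-25). A split of this word by class, chosen after its share was seen, gave 30.4% in promoters and 47.1% elsewhere (Fisher's exact p = 0.00166). With nuclear summits only, the shares were 32.2% and 48.2% (Fisher's exact p = 0.00323). The other preset words did not pass the threshold. CAGGTA was in 4 summit windows and 9 left windows, CAGCTG in 10 and 8, CACGTG in 12 and 10, GATAAG in 5 and 11, and TGACTCA in 3 and 2 (adjusted p from 0.623 to 1).

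Of all hexamers, 493 differed between summit windows and windows 500 bp to either side, 283 of them higher at summits and 210 lower (Fisher's exact test, Benjamini-Hochberg adjustment). The highest ranks were GAGAGA, AGAGAG, CGTCTC and GACGCA, the last in 20.8% of summit windows and 2.25% of flanking windows (Fisher's exact test, adjusted p = 1.04e-20). AAAATT was lower, in 16.9% against 42.7% (Fisher's exact test, adjusted p = 1.30e-15). AGAGAC (24.4% of summit windows), CGTCTC, which reads GAGACG on the other strand, and GACGCA overlap in sequence. Whether they and GAGAGA are parts of a longer word was not tested. None of the higher hexamers held CACCT. Mean GC content was 47.2% ± 10.2 (SD, n = 357 windows) at summits and 36.1% ± 9.42 (SD, n = 713 windows) in the flanks, and the hexamer calls were not corrected for it.

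**Figure D5:**
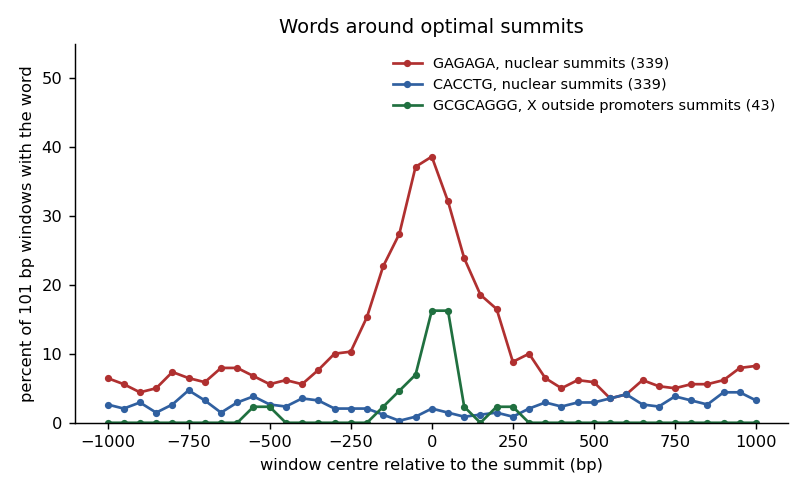
Percent of 101 bp windows holding GAGAGA or CACCTG (339 nuclear summits) or GCGCAGGG (43 X-linked summits outside promoters, a word chosen after the data were seen), by the distance of the window centre from the summit in bp. GAGAGA peaks at the summit at 38.6%, and CACCTG shows no peak there, at 2.06%.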

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

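The settings limited to nuclear summits and to regions found in both replicates were chosen after seeing the data. No paired analysis was possible because the series holds 1 group. The promoter share (46.5% to 70.0%), the distance to starts and the X share kept their direction and passed the threshold under all alternatives run, as did the ribosomal and chemoreceptor lists. The top of the joint list is the optimal set, so it tests nothing. Without a read depth, differences in score between libraries could not be weighed.

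The share found in both replicates moved with the rule: 66.7% within 50 bp, 96.4% within 200 bp, 98.9% for a 1 bp overlap, 93.8% for 50% overlap, and 92.1% among the 178 regions of highest score. The shared top regions were 33.9% within 50 bp, 49.9% for a 1 bp overlap, 27.7% for the top 1000 and 13.1% for the top 5000. Pearson r of log2 score across regions found in both replicates was 0.567, above the planned measure of correlation, which is not given here; regions are not independent replicates. Among those 178, 2 lists and 238 hexamers passed, and 1 replicate alone gave 3 to 4 lists and 328 to 456 hexamers. Replicate 1 alone gained the pan-neuronal list (Fisher's exact test, adjusted p = 0.00121, up to 0.857 under the other settings) and lost the respiratory chain list. CACCTG turned to higher at summits among the 178 (2.81%) and as CACCT (9.27%), with exact McNemar adjusted p of 0.793 and 1. Within 100 bp it was in 8 summit and 21 left windows (exact McNemar p = 0.0192, adjusted 0.0671), toward lower at summits. The 178 regions give fewer windows and genes to test; otherwise the cause was not tested.

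At zag-1, the top 5000 regions gave 1 region in either replicate (permutation p = 0.79), where random windows hold too few to test. A 5000 bp window gave 0 in both, past the threshold in replicate 1 (permutation p = 0.044) and not in replicate 2 (permutation p = 0.077). At unc-119 the top 5000 of replicate 1 gave 0 (permutation p = 0.29), below the median of random windows. Heterochronic genes lost the call among the 178 (Fisher's exact test, adjusted p = 0.494). Respiratory chain genes lost it there (0.291), without either replicate (0.197 to 0.656), with regions found in both (0.133), with no distance limit (0.0514) and against genes of the joint list (0.139). Their odds ratio was 6.06 among the 178 and 5.79 with no limit, close to 6.11, and 2.97 from replicate 1 alone.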

Other observations

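The tests of CACCTG as a direct site, of signal order on the X chromosome, of the X word in each replicate alone, and of the ends and the gene or GC content at zag-1 were chosen after the results were seen. All of the patterns here came from these same data, so each explanation is a hypothesis.

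The X chromosome regions included a set with one word. GCGCAGGG, the core of the MEX element that recruits the dosage compensation complex to X in hermaphrodites, lay within 100 bp of 11 optimal summits, all on X, and of 0 of 252 autosomal summits. They lay near W02H3.3, cest-16 (in an intron of mom-1), nspc-17, Y41G9A.17, F20B6.9, xol-1, gtr-1, F22H10.2, C41A3.2 (in a coding exon of pks-1), ins-39 and T24D8.6; several of these names were chosen after their values were seen. The word occurs 81 times on X and 233 times on the autosomes, with 15 and 0 of these within 100 bp of an optimal summit. Of the 25 highest nuclear regions, 14 were X-linked outside promoters. The median score of the 43 X-linked regions outside promoters, 49.6, against 43.04 for the other 296, was not past the threshold (two-sided permutation p = 0.094).

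For these X-linked regions outside promoters, 9 of 43 (20.9%, interval 10.04 to 36.04) held the word, against 0 of 94 autosomal regions outside promoters (Fisher's exact p = 1.57e-05). GC-matched X windows held it in 0.240% (95% range 0 to 2.33), so GC content alone does not give this share. The word occurs only 81 times on X, so such windows could hardly have held it often, and the test is weak. A single replicate as the source is argued against by the highest regions of each. In replicate 1 the word was in 15.5% of 58 X-linked regions outside promoters and in 2 of the more numerous autosomal ones (Fisher's exact p = 0.00143). In replicate 2 it was in 22.2% of 45 and in 0 (Fisher's exact p = 3.13e-06). A candidate explanation is that part of the signal lies at dosage compensation recruitment sites; whether ZAG-1 binds there or open chromatin at such sites is pulled down in any library was not tested, and most of the 43 lack the word.

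The GAGAGA share at promoter summits was above that at promoters in general. At the same distances from starts of genes without an optimal region, GAGAGA was in 6.97% of windows (95% range 3.47 to 10.4), against 32.2% at the 202 nuclear promoter summits. The word was also higher in the highest regions of each replicate alone (exact McNemar p = 2.54e-17 or lower). GC content stays open in part. GC-matched starts held the word in 12.9% (95% range 8.42 to 17.3), below the 32.2% at promoter summits. This argues against GC content alone at those summits. The range spans the limit set for this test, so a part played by GC content cannot be told apart. Direct binding through CACCTG at most regions is argued against by its share of 1.97%. The series holds 1 group, so no biological explanation could be tested between groups.

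Around zag-1, positions 3839720 to 3881528 of chromosome IV (41809 bp, 8 genes) held no region of either replicate. The gap of replicate 1 that spans it, 42228 bp, was longer than 99.98% of 29977 gaps, and that of replicate 2, 49327 bp, than 99.96% of 26177. A given gene falls in a long gap more often than in a short one, so these shares overstate how unusual the stretch is. The random windows of fixed length described above do not have this bias. Repeated sequence is argued against by 1.18% non-unique 36-mers against a median of 4.93% in random windows. The stretch was not low in genes or GC, with 8 genes and 38.9% GC against medians of 8 and 35.4% in random windows. This argues against few genes or low GC there. Of 761 windows matched in both to zag-1 and 20000 bp on either side, 3.02% held as few regions in both replicates. Their medians were 12 and 10 regions in replicates 1 and 2, against 3 and 1 at zag-1. The 3.02% lay between the limits of 1% and 5% set for this test, which therefore did not decide. Extra copies of the transgenic stretch in the control may thin the regions there, and would end at the same place in both replicates. This cannot be told apart. Around unc-119, which may also be in extra copies, the full lists held 15 and 17 regions, against medians of 14 and 12. Within 5000 bp of unc-119 they held 6 and 5, against 5 and 4. How much unc-119 sequence the transgene carries was not examined, so this does not decide. At the zag-1 stretch replicate 2 sets the left end and replicate 1 the right end, so only the other replicate is informative at each. On the left the first region of replicate 1 lay 419 bp away, and 87.9% of random positions were as far from a region. On the right replicate 2 had none for a further 7518 bp, as far as at 17.3% of random positions. The control was not analysed here.

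Mitochondrial regions covered 40.6% of the molecule in replicate 1 and 47.3% in replicate 2, between the bounds of 25% and 50% set beforehand for a whole-molecule excess of reads. Of the 17 regions of replicate 1, 12 had a summit of replicate 2 within 100 bp, against a median of 5 in random placements (one-sided permutation p = 0.0002). Of the 339 nuclear summits, 9 (2.65%, interval 1.22 to 4.98) lay within 500 bp of a tRNA gene, against 0.612% in random placements (two-sided permutation p = 0.0006).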
